A study of Mus musculus with 3 samples.

How the data were processed

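HSF2 ChIP DNA and Input DNA from adult mouse testis were hybridised together on 3 NimbleGen promoter arrays, 1 biological replicate per array. Per the labels' protocols, testes were cross-linked with 1% formaldehyde, quenched with 125 mM glycine and sonicated to fragments of about 100 to 500 bp. Chromatin was precipitated with an HSF2 antibody after preclearing with protein G beads. Per the labels, the whole ChIP sample but 20 ng of Input went into ligation-mediated PCR, so both DNAs were amplified and amplification bias can differ between them. No precipitation with a control antibody was analysed here, so a ratio above 0 measures recovery in the ChIP over Input and not HSF2 specificity.

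The deposited scanner files give 1 intensity per probe and channel on a linear scale, extracted with NimbleScan 2.3.3 for replicates 1 and 2 and 2.3.4 with local alignment for replicate 3, per the file headers. No background subtraction is recorded there. The deposited value table holds log2 ratios for 26129 promoters, and its making is not given in the sources used here. Set against the scanner values, each column closely followed promoter means of loess-normalized log2(ChIP/Input), with r above 0.999 and slopes of 1.00 on all 3 arrays. The 146 promoters it lacks are exactly those with 1 or 2 probes, and its column medians are 0.0145, 0.0163 and -0.0152. Scale, centring and direction were found in this way from the values. Its direction opposes the dye fields of the labels and follows the channel descriptions.

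Log2 of ChIP over Input intensity was taken for each promoter probe as given, with replicate 2 read from the swapped dyes, and the array median was subtracted (0.02, 0.06 and 0.50 before centring). Loess was not used in the main values because many promoters may shift one way in ChIP, and normexp was run as an alternative only. Positions along the tile were taken from the files; the 6.15% of promoter probes before position 3501 were left out of the comparison along it. The 1540 random-sequence and 344 E. coli control spots were left out. Probes were averaged per promoter, and overlapping windows of 250 bp either side of a probe start with at least 4 probes were averaged as well. An intercept was tested against 0 with limma 3.58.1 lmFit and eBayes in R 4.3.3, with Benjamini-Hochberg adjustment over all promoters or all windows and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9. Where the median is subtracted, the ratio shows unequal recovery within an array and not an absolute amount.

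Promoters were assigned to classes from the chromosome part of the probe names, in mm5 coordinates per the design name in the file headers. UNR was read as unplaced sequence and the suffix R as sequence assigned to a chromosome without a position, and the labels explain neither. XR and YR were counted with the X and the Y. The planned gene lists were not tested, and no gene is named: the gene table used here is of GRCm38 and 0 promoter IDs matched it. The naming rule, written before the data were examined with the tests and thresholds, then left the 2 called promoters with the highest means and the 2 with the lowest, of which 1 existed. The classes of unplaced and R-suffixed sequence, the log2 0.5 limit on every array, the short-tile limit, the dye term after loess and the class means were added after the data were seen.

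The fit was tested on simulated arrays of 26275 promoters, with 50 promoters changed at each size. Each promoter's spread was drawn from the observed SDs over 3 arrays. Such SDs vary more between promoters than the true spreads, so recovery on the real arrays can differ from the simulated one. The fit recovered 0% at log2 0.5, 28% at 1, 78% at 1.5 and 76% at 2, with 4 false calls. With 1 common spread for every promoter it recovered 80% at log2 0.5 and 100% at the larger sizes, with 5 false calls. Unchanged promoters were simulated with no signal shared between arrays, so the false calls do not cover effects that the real arrays share. Alternatives were normexp with an offset of 50, loess, Tukey centring, scale normalization, a dye term, leaving out dim probes, probes at or above 65000 or each replicate, medians of probes, robust empirical Bayes, the deposited table, at least 8 probes, stricter thresholds, windows of 150 and 500 bp and the dyes of the label fields. Leaving out replicate 3 is also the value within the first extraction version; the other version holds 1 array and gives no spread. Each array held both DNAs, so extraction version and ChIP are not confounded.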

Results

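HSF2, a heat shock transcription factor that is abundant in the testis, was mapped by chromatin immunoprecipitation on promoter arrays (ChIP-chip) in testes of adult wild-type mice of 60 days. The arrays held HSF2 ChIP DNA in one dye and Input DNA, the reference chromatin sample, in the other. There were 3 biological replicates, 1 per array, and the labels do not say whether a replicate was 1 animal or a pool. Each array tiled 26275 promoters with 386424 probes, and 96.0% of promoters had 15 probes. The median probe intensity of the ChIP channel was 1728, 1109 and 2946 on replicates 1, 2 and 3, and that of the Input channel was 1640, 949 and 1982. In the ChIP channel 22.4%, 26.5% and 33.8% of promoter probes were brighter than 95% of the random-sequence control probes, and in the Input channel 20.4%, 20.7% and 29.4% were. The number of arrays, 3, limits the precision of every value.

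All ratios are log2(ChIP/Input) centred on each array's median, and their direction is likely rather than settled. The channel descriptions place ChIP DNA in Cy5 on replicates 1 and 3 and in Cy3 on replicate 2, whereas the dye fields of the same labels name the opposite dye on all 3. The authors' deposited ratios followed the channel descriptions on every array, with r across promoters of 0.99, 0.99 and 0.97. A second planned check was the skew of window means, which is positive where the upper tail is longer. It was 0.54, 0.35 and -0.016 on replicates 1, 2 and 3, and so favoured this direction on replicates 1 and 2 only. With the dyes of the label fields, every higher value would be a lower one. The replicates shared part of their signal once the dye swap was undone. Across promoters, which are not independent replicates, Pearson's r was 0.37 between replicates 1 and 2, 0.42 between 1 and 3 and 0.38 between 2 and 3, and Spearman's rho was 0.37, 0.42 and 0.38. Left unturned, the pairs that include replicate 2 had r of -0.37 and -0.38.

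The comparison of HSF2 ChIP with Input asked which promoters HSF2 occupies in the testis. A ratio above log2 0.5, a 1.41-fold enrichment, was reached on all 3 arrays by 207 promoters (0.788%), and 41 promoters were below -0.5 on all 3. Under normexp these counts were 845 and 353, and under loess 162 and 61. Shuffling promoters within arrays gave 9.29 and 1.16 promoters on average, with highest counts of 22 and 7 (permutation p = 1e-04 for both, one-sided, the smallest that 10000 shuffles can give). Shuffling breaks every link between arrays, so this p restates that the arrays shared signal. It cannot tell HSF2 binding from any other effect that the arrays shared. Promoters of sequence not placed on a chromosome supplied 47 of the 207, promoters of the numbered chromosomes 131, the X 9 and the Y 5. The other 15 came from sequence named for a numbered chromosome with the suffix R. Merging promoters within 100 kb of each other in the coordinates of the array design left 192 groups of the 207.

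Promoter by promoter, 5 were enriched and 1 was depleted at an adjusted p of 0.0481 (limma, two-sided, Benjamini-Hochberg over 26275 promoters, n = 3 arrays). The highest mean was that of MMUS0407S00034391 on sequence 5R, with only 6 probes, from 486775 to 486825 in the mm5 coordinates of the array design. Its log2 ratio was 1.95, 1.72 and 1.45 on replicates 1, 2 and 3, a mean of 1.71 ± 0.249 (SD, n = 3) or 3.26-fold. MMUS0407S00035370, in unplaced sequence from 92430193 to 92430343, had 1.54, 2.01 and 1.57, a mean of 1.71 ± 0.265 (SD, n = 3). The remaining 3 enriched promoters, given here after their values were seen, also lay in unplaced sequence. They began at 28318239, 94135931 and 88496127, with means of 1.63 ± 0.098, 1.52 ± 0.186 and 1.30 ± 0.121 (SD, n = 3). The one at 28318239 had only 5 probes. The depleted promoter, MMUS0407S00034994, lay in unplaced sequence from 14331540 to 14331740 and had -1.25, -1.44 and -1.26, a mean of -1.32 ± 0.108 (SD, n = 3). All 6 were tiled over 250 bp or less, a property of 5.64% of promoters (a limit chosen after the values were seen, at the span of the widest of the 6), so that their probes lay close together and were not independent readings. Such tiles were more common in the classes of the 6, at 91 of 464 unplaced promoters and 93 of 568 on R-suffixed numbered sequence. Of 1095 autosomal promoters with such tiles, 0 were called. Promoter IDs matched no entry of the gene table used here, and no gene is named.

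The 5 and 1 calls stood close to the threshold. At an unadjusted p below 0.05 in limma, 3328 of the 26275 promoters were enriched and 1915 depleted. Loess normalization left 0 calls with limma (2867 enriched and 2166 depleted at an unadjusted p below 0.05), and leaving out replicate 1 or replicate 3 left 0, whereas leaving out replicate 2 gave 22 enriched and 7 depleted. The means of MMUS0407S00034391, MMUS0407S00035370 and MMUS0407S00034994 stayed near their size, at 1.75, 1.74 and -1.23 under loess, 1.58, 1.79 and -1.35 without replicate 1 and 1.83, 1.78 and -1.34 without replicate 3. Their adjusted p was 0.058 under loess, 0.204 to 0.215 without replicate 1 and 0.0731 without replicate 3 (limma, Benjamini-Hochberg). Requiring at least 8 probes left 0 calls, with a lowest adjusted p of 0.0639 (limma, Benjamini-Hochberg). Normexp gave 24 enriched and 11 depleted and scale normalization 17 and 9. A model with a dye term called 2003 enriched and 761 depleted promoters, but its residual spread came from replicates 1 and 3 alone, and after loess it called 471 and 194. Sliding windows of 250 bp either side, suited to the 100 to 500 bp fragments, gave 0 enriched and 0 depleted of 338848 with limma. At an unadjusted p below 0.05 in the same fit, 35407 windows (10.4%) were enriched and 25076 (7.40%) depleted. With the dye term 0 windows were enriched as well.

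The ratio depended on probe brightness on every array. With probes parted by brightness into 10 equal groups, it went from the dimmest group to the 8th from -0.15 to 0.08 on replicate 1, from -0.18 to 0.25 on replicate 2 and from -0.28 to 0.16 on replicate 3, and in the brightest group it was 0.07, -0.13 and -0.06. Promoters of unplaced sequence and of the Y were brighter than the autosomes, at a mean log2 intensity of 11.2 and 12.2 against 10.8.

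**Figure D1:**
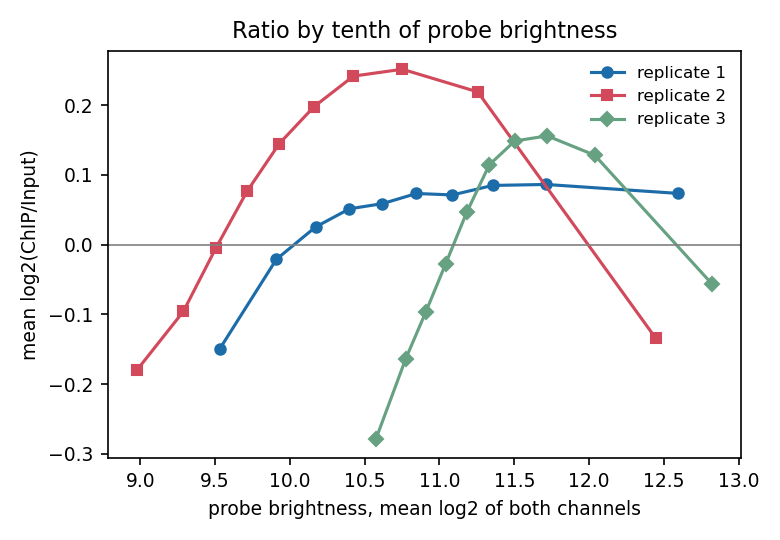
Mean log2(ChIP/Input) (vertical axis) of promoter probes in 10 groups of equal size by brightness, against the mean log2 intensity of both channels (horizontal axis), one line per replicate. The dimmest group lies below 0 on all 3 arrays, at -0.15, -0.18 and -0.28.

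By class of sequence, promoters of unplaced sequence stood above the autosomes on all 3 arrays. Their mean log2 ratio exceeded that of the 23863 autosomal promoters by 0.23, 0.22 and 0.18, a mean of 0.21 ± 0.025 (SD, n = 3). Among the 464 unplaced promoters 10.1% exceeded log2 0.5 on every array (exact binomial 95% interval 7.54 to 13.2), against 0.549% of autosomal promoters (0.459 to 0.651). The odds ratio was 20.4 (14.1 to 29.1; Fisher's exact test, two-sided, Benjamini-Hochberg p = 2.18e-39 over 5 classes). It was 8.94, 13.2 and 9.60 without replicates 1, 2 and 3, 5.33 under normexp, 31.9 under loess, 33.3 with the deposited table and 35.7 with medians of probes. Promoters on R-suffixed numbered sequence reached 2.64% (15 of 568, odds ratio 4.91, Benjamini-Hochberg p = 4.21e-06 by the same exact test). Their mean was 0.03 ± 0.018 (SD, n = 3) above the autosomes. Of the 15, 5 lay among the 20 promoters of 14R (25%), far above the share of the class. Another 5 lay among the 216 of 7R (2.31%), near that share. The lower tail was wider in both classes too: 4 unplaced promoters (0.862%) and 4 on R-suffixed sequence (0.704%) were below -0.5 on every array, against 0.134% of autosomal promoters (odds ratios 6.47 and 5.28, Fisher's exact test, two-sided, Benjamini-Hochberg p = 0.0157 for both). With the dyes of the label fields these shares would be the enriched ones. Neighbouring and related promoters are not independent, and these exact tests treat them as if they were. The ranking of unplaced promoters against all others by limma's camera gave a Benjamini-Hochberg p of 1.26e-07 with a preset correlation, and adjusted p = 0.532 with an estimated correlation. By camera the Y had a Benjamini-Hochberg p of 0.00173 and the X of 0.030 with the preset correlation, and both had adjusted p = 0.735 with an estimated correlation.

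**Figure D2:**
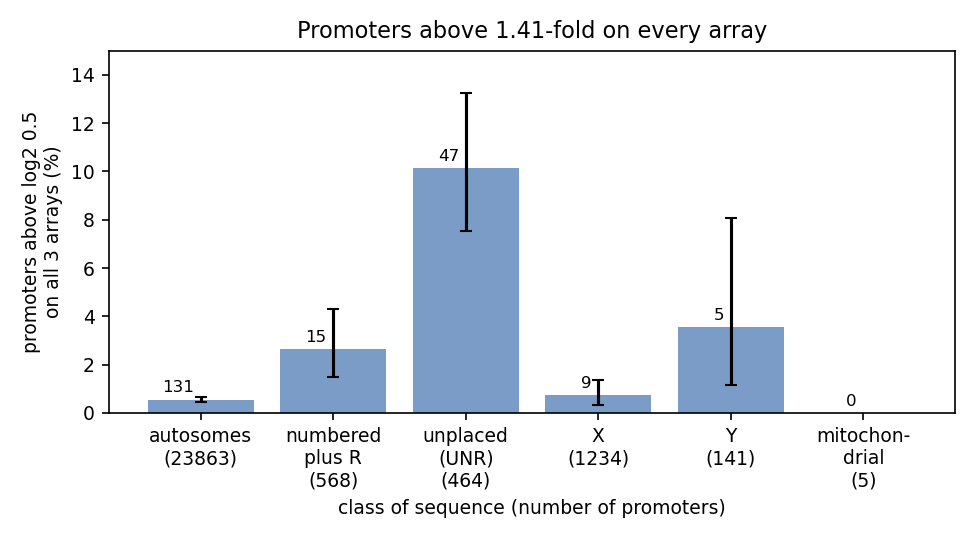
Share of promoters (%, vertical axis) above log2(ChIP/Input) 0.5 on all 3 arrays, by class of sequence (horizontal axis, promoters per class in brackets), with bars for the share, exact binomial 95% intervals and the count above each bar. Unplaced sequence stands at 10.1% and the autosomes at 0.549%.

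The sex chromosomes were compared with the autosomes as planned; both carry multi-copy genes active in the testis. No Y or X promoter was called enriched by limma (0 of 141 and 0 of 1234), nor was any of the 23863 autosomal promoters, so the planned Fisher's exact test had no calls to compare. Of the Y and X promoters 46 and 83 were enriched and 14 and 77 depleted at an unadjusted p below 0.05, beside 2951 and 1754 of the 23863 autosomal promoters. Y promoters had mean log2 ratios of 0.50, 0.06 and 0.01 on replicates 1, 2 and 3. Their mean of 0.16 ± 0.273 (SD, n = 3) above the autosomes was within the spread between arrays and rested on replicate 1, without which it was 0.0026. On every array 5 Y promoters (3.55%, exact interval 1.16 to 8.08) exceeded log2 0.5, an odds ratio of 6.66 against the autosomes (Fisher's exact test, Benjamini-Hochberg p = 0.00211). Y promoters averaged 0.50 on replicate 1, so the limit was easier to pass there, and the test treats them as independent. Tiles of 250 bp or less held 2 of the 5, among 14 such Y promoters. On every array 0 Y and 0 X promoters were below -0.5. X promoters differed from the autosomes by -0.05 ± 0.049 (SD, n = 3), also within the spread. The difference was -0.07, -0.02 and -0.05 without replicates 1, 2 and 3 and -0.0060 under loess. Of the X promoters 0.729% exceeded log2 0.5 on every array (odds ratio 1.33, 0.594 to 2.61). With the dye term, limma called 27 Y and 55 X promoters enriched, 19.1% and 4.46% against 7.24% of autosomal promoters, and 3 and 25 depleted, 2.13% and 2.03% against 2.91%. With the dyes of the label fields, the depleted shares would be the enriched ones. The 5 mitochondrial promoters had 0.20, -0.67 and -1.22, a mean of -0.56 ± 0.718 (SD, n = 3). They differed from the autosomes by -0.59, and by -0.98, -0.52 and -0.28 without replicates 1, 2 and 3, and their probes were far brighter, at a mean log2 intensity of 14.5 against 10.8 on the autosomes.

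**Figure D3:**
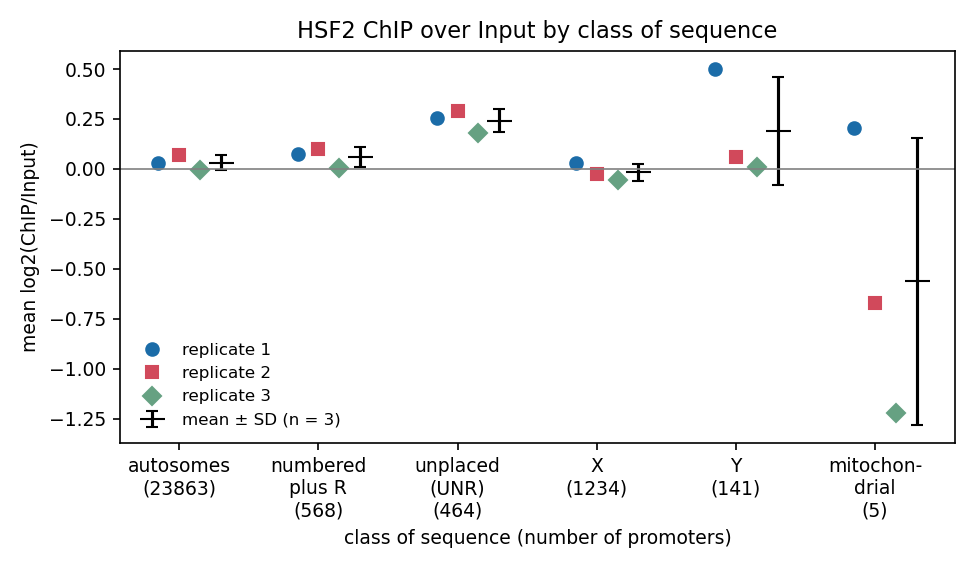
Mean log2(ChIP/Input) of each class of sequence (vertical axis) on each array, with coloured points for replicates 1 to 3 and black bars for the mean ± SD over 3 arrays; promoters per class are in brackets. Unplaced promoters lie at 0.26, 0.29 and 0.18, and Y promoters at 0.50, 0.06 and 0.01, on replicates 1, 2 and 3.

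Along the tiled sequence, the ratio over all promoters was higher at the start than at the end. The first 500 bp of the tile (positions 3501 to 4000 of the tiled sequence) averaged 0.10 ± 0.060 and the last 500 bp (4501 to 5000) -0.02 ± 0.030 (SD, n = 3). The difference was 0.17, 0.13 and 0.06 on replicates 1, 2 and 3, a mean of 0.12 ± 0.057 (SD, n = 3), and an exact sign-flip test of 3 arrays cannot go below p = 0.25. The 207 promoters above log2 0.5 on every array went the other way, with differences of -0.24, -0.12 and -0.32, a mean of -0.23 ± 0.097 (SD, n = 3). Within promoters with probes at both ends, the mean was 0.13 ± 0.053 over 21082 promoters and -0.28 ± 0.128 over 111 of the 207 (SD, n = 3). The 207 were chosen for a high mean over these same probes, which are denser in the last 500 bp. That choice can itself raise the end of the tile, so their opposite direction is no independent result. None of the 5 called promoters had probes at both ends. Where the transcription start lies in the tile is not given in the sources used here.

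**Figure D4:**
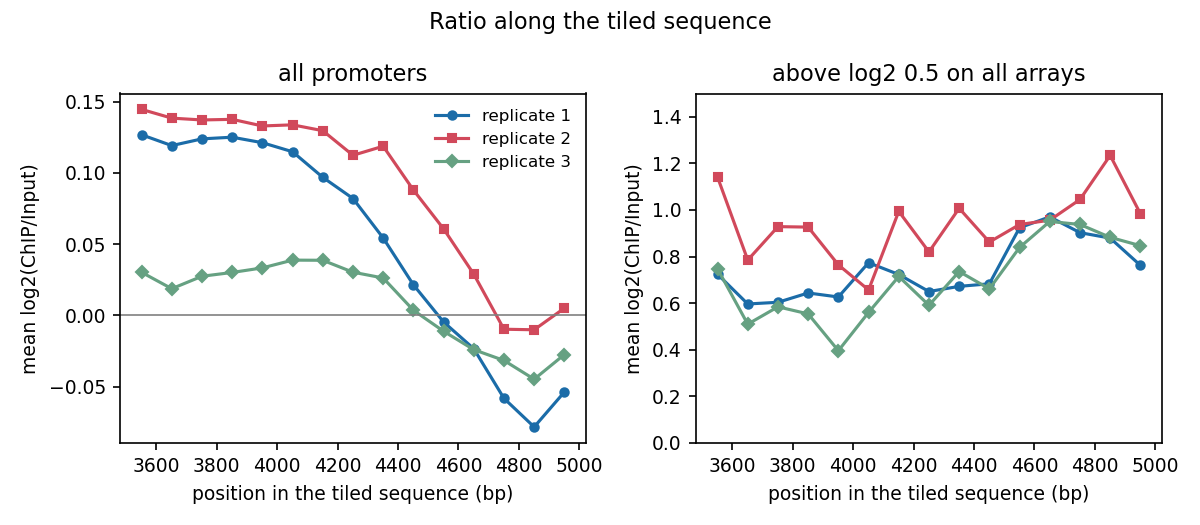
Mean log2(ChIP/Input) (vertical axes) in 100 bp bins of position along the tiled sequence in bp (horizontal axes), one line per replicate, for all promoters (left) and for the 207 above log2 0.5 on all arrays (right). Over all promoters the ratio is lower in the last 500 bp, by 0.12 on average, and in the 207 the difference of first minus last 500 bp is -0.23. The 207 were chosen on these same values.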

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

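Control spots outside the comparison held signal, and both values were looked up after the arrays had been analysed. The E. coli control probes exceeded the random-sequence probes of the same Input channel by log2 0.98 on replicate 2, and by 0.31 and 0.70 on replicates 1 and 3. The first probe of the first E. coli sequence exceeded them by 5.82 in the Input channel of replicate 2, and by 1.93 and 3.06 on replicates 1 and 3, against 0.88, 1.51 and 2.13 in the ChIP channel of replicates 1, 2 and 3. Groups of 3 arrays are too small for the test of single outlying samples, and there was no second group to compare.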

How the results depend on the processing

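The class differences, the alternatives of the agreement between arrays, the counts above log2 0.5 and below -0.5, the odds ratios, the dye term after loess and the difference along the tile without 1 replicate were added after the data were seen. The other alternatives were planned. Enriched and depleted promoters numbered 24 and 11 under normexp, 17 and 9 under scale normalization, 16 and 7 with medians of probes, and 2003 and 761 with the dye term, whose residual spread comes from replicates 1 and 3 alone, and 471 and 194 with the dye term after loess. They numbered 0 and 0 under loess, with the deposited table, with at least 8 probes and at an adjusted p of 0.01, and 1 and 5 with the dyes of the label fields, which turns every sign. Leaving out 1 replicate gave 0 to 22 enriched and 0 to 7 depleted. Tukey centring, dim or saturated probes left out, robust empirical Bayes and a log2 minimum of 0.5 gave 5 and 1. The 5 enriched promoters were all among those of normexp, the dye term, medians and the fit without replicate 2, and 3 among those of scale normalization. Called Y promoters numbered 27 with the dye term, 1 with medians and 0 to 2 without 1 replicate, and called X promoters 55 with the dye term and 0 to 1 without 1 replicate. Promoters with an enriched window numbered 0 in all 12 alternatives, with a lowest adjusted p of 0.0646 under the dye term (limma, Benjamini-Hochberg) and 0.127 to 0.410 in the others. Promoters above log2 0.5 on every array numbered 845 under normexp and 406 to 594 without 1 replicate, where fewer arrays must pass, and promoters below -0.5 numbered 353 and 101 to 211. Unplaced promoters above 0.5 numbered 66 under normexp and 61 to 72 without 1 replicate, and their odds ratio against the autosomes was 8.94 to 13.2 without 1 replicate and stayed above 5 in all alternatives. Unplaced sequence exceeded the autosomes by 0.20 to 0.26, the highest under normexp, in the 13 alternatives run for it, which leave out the dyes of the label fields. The causes of the other shifts were not tested. The lists of genes, with camera, fry and all their alternatives, were not run. ChIP and Input were paired within each array by the ratio itself. Signal over background limits all of this, since most probes lay within the range of the random-sequence probes.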

Other observations

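The counts of called Y and X promoters with a dye term and the difference along the tile after loess were planned; the other tests in this part were chosen after the results were seen. Outside unplaced sequence, a few bins of 1 Mb held 3 or more promoters above log2 0.5 on every array, in mm5 coordinates. On chromosome 2, in adjacent bins from 175274349 to 176742872, 7 of 13 promoters passed. The 13 averaged 0.58, 0.81 and 0.44 on replicates 1, 2 and 3, a mean of 0.61 ± 0.185 (SD, n = 3). None of them was called, with a lowest adjusted p of 0.115 (limma, Benjamini-Hochberg). On chromosome 9, from 109042765 to 109915403, 3 of 20 passed, and on chromosome 4, from 41010859 to 41981748, 3 of 35. Bins with 3 were not tested on their own against random placement. Of 9 promoters on sequence 14R between coordinates 176508 and 777427, which need not be distances along a chromosome, 4 passed, and the 9 had a mean of 0.52 ± 0.15 (SD, n = 3).

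Autosomal promoters above log2 0.5 on every array filled 1 bin of 1 Mb on chromosome 2 with 4 members. In 10000 shuffles along the autosomes the fullest of 2328 bins held 2.25 on average and 5 at most (permutation p = 0.012, one-sided). Pairs of such promoters 2 to 100 kb apart numbered 4 against a mean of 1.44 in shuffles (permutation p = 0.06, one-sided). Random placement along the autosomes thus gave as many pairs in over 5% of draws but seldom a bin as full. The bin count, unlike the pairs, kept promoters under 2 kb apart, whose tiles can overlap. Shuffling these as independent can understate how often a bin fills.

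With a dye term and no loess, limma called 27.8% of unplaced promoters enriched (129 of 464, odds ratio 4.94 against the autosomes, Fisher's exact test, two-sided, Benjamini-Hochberg p = 4.79e-39). It called 19.1% of Y promoters (odds ratio 3.04, 1.91 to 4.67) and 4.46% of X promoters (odds ratio 0.598, 0.446 to 0.788). Depleted in that fit were 4.09% of unplaced, 2.13% of Y, 2.03% of X and 2.91% of autosomal promoters, which would be the enriched shares with the dyes of the label fields. In the same fit the dye coefficient itself was called for 3 promoters.

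Unplaced promoters exceeded autosomal promoters on all 3 arrays, and 4 technical explanations were tested. The excess was 0.22 ± 0.020 (SD, n = 3) over autosomal promoters of like tiled span, 0.22 ± 0.0093 over those of like brightness and 0.22 on replicate 2, where the dyes were swapped. Tiles over 250 bp alone left 0.20 ± 0.030 (SD, n = 3), with 33 of 373 promoters above log2 0.5 and 2 below -0.5 on every array, against 122 and 30 of 22768 autosomal promoters, so none of span, brightness and dye accounts for the whole excess. Identical copies stay open: keeping 1 promoter per probe spacing left 0.21 ± 0.029 (SD, n = 3) but kept 399 of 411 promoters, and keeping 1 per 100 kb of the design's coordinates left 284 promoters with 0.19 ± 0.038 (SD, n = 3). Amplification bias between ChIP and Input, base composition, diverged repeats and recovery without HSF2 stay open, and the design holds no group to test a biological explanation, so binding of HSF2 there could not be separated from these.

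Y promoters stood 0.47 higher on replicate 1 than on the mean of replicates 2 and 3. Matching each Y promoter to autosomal promoters of like brightness on the same array left 0.36. The gap rests on 1 array, and 2 others give too little of the spread between arrays to exclude the brightness trend or chance. A difference between animals or preparations stays open as well, and no biological explanation was tested.

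The fall of the ratio along the tiled sequence was 0.14 ± 0.047 (SD, n = 3) after loess on brightness, against 0.12 ± 0.057 before it, so a brightness trend is unlikely to be its whole source. Base composition along promoters stays open, and no biological explanation was tested.

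ChIP and Input can be assigned within the 3 arrays in 4 ways, too few for a share under 0.05. The real assignment called 6 promoters in either direction and the highest other 0, so 1 of the 4 reached the real count, and with the dye term 2764 against 3, again 1 of 4. For windows all 4 gave 0, by limma with Benjamini-Hochberg adjustment. At an unadjusted p below 0.05 in limma the real assignment gave 5243 promoters and the others 445 to 470. The arrays shared signal, with Pearson's r of 0.37 to 0.42. Without a dye term, turning 1 array moves that signal into the residual spread. With the dye term, turning replicate 2 leaves the residual spread, from replicates 1 and 3, as it was. The intercept and the dye coefficient then change places, and the 3 calls are those of the dye coefficient itself. Either way the counts of the other assignments fall, so the contrast restates the agreement between arrays and gives no level expected by chance.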
